A study of Mus musculus with 24 samples.

How the data were processed

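Polyadenylated RNA from 24 mouse samples in 6 groups of 4 was compared. Per the labels, the source was kidney tissue of C57/BL6 mice, RNA was isolated with a Qiagen kit, and stranded Illumina TruSeq libraries were made after poly(A) selection. Hap-I and Hap-II are the labels' names for lines carrying haplotype I or haplotype II of the human angiotensin receptor type 1, and C57 is the group without either. The design text states 4 animals per group. The labels give no sex, batch, date or exact age.

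The authors deposited a single table of TPM (transcripts per 1e+06) per gene and library, with 30153 mouse gene identifiers and no gene names. The submitters' processing notes name kallisto, DESeq2 and the genome build GRCm38 without versions or roles. The annotation release, the summing of transcripts to genes and any filter are not given in the sources used here. The deposited TPM of a library sum to between 904693 and 944019, so a part of the quantified transcripts lies outside the table. TPM keep no read depth, so depth per library is unknown and no counting interval or detection floor is given. A value of 0 is reported as listed at 0. All 8 housekeeping genes checked were above 0 in every library, and 6366 genes were listed at 0 in all 24. At most 1 value above 0 was identical in any pair of libraries. Columns were matched to samples by the code in the sample title, which is also the column name. Titles carry the letters A, B and C for the groups on western diet and S for the others, and absence of the diet is inferred from labels that do not state it.

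Identifiers were matched to symbols and coordinates in GENCODE release M21, on GRCm38. Of the identifiers, 29732 matched and 421 did not. Genes with a near-identical copy were found by shared words of 31 bases between annotated transcripts, at a minimum share of 50 percent. Because pseudo-alignment can divide reads between copies unevenly, such genes are reported as uncertain, and so are immunoglobulin segments. The search covered only genes called for haplotype and for age on western diet. Genes named in other comparisons may therefore have copies that are not marked.

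Expression was tested as log2(TPM + 1). A gene was kept at 1 TPM or more in at least 4 libraries, which left 15200 genes. Fold changes on this scale understate the change of weakly expressed genes. A mean per group was fitted to all 24 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), so that the 6 groups shared a residual spread. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The 7 comparisons were age on western diet, haplotype on western diet, age without the diet, the diet in adults and in aged mice, Hap-I against C57, and the difference of the diet effect by age.

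Of 50 gene lists with 922 genes, 49 kept at least 4 genes and were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance to 1 side, were alternatives. The number of list members past the threshold is given over all genes tested and adjusted over the list alone. Where camera picked the list from the same data, the second count is descriptive and no further evidence. A mean of log2(TPM + 1) over each list and library was compared between groups by a two-sided exact permutation test, for which 4 against 4 libraries allow no p below 0.0286.

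Genes were named by a fixed rule. It took, first, up to 8 higher and 8 lower genes with the largest change among those past the threshold, with a mean of at least 5 TPM in the higher group and no overlap between libraries. Predicted genes, pseudogenes and genes without a symbol were left out. It took, next, up to 4 members of each list called by camera. It took, last, a fixed panel of 24 renin-angiotensin, injury, inflammation, matrix, redox, ageing, lipid and clock genes, of which Agtr1b, Il6 and Cdkn2a fell below the filter. The difference of the diet effect used 6 genes a side and no panel. The groups, tests, gene lists, naming rule and settings varied as checks were fixed before the data were examined.

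Settings fixed beforehand as checks were a pseudocount of 0.1, no low filter, a filter of 5 TPM, median-of-ratios rescaling, quantile normalization, removal of mitochondrially encoded genes, array weights, only the compared groups, each library left out in turn and the title number as a block. Further ones were chosen after seeing the data. These left out 8 libraries, filtered on the other 16, used the mean of 4 Y-linked genes as a covariate, left out the 2 libraries with the fewest genes, removed 6 mitochondria-like pseudogenes, summed gene copies, and used C57 in place of the Hap-I groups without the diet. Markers of neurons, astrocytes, oligodendrocytes and nephron segments, 39 in all, were also listed after the data had been seen.

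The fitting procedure was tested on simulated data built from the real means and spreads, with 15200 genes of which 100 changed 2-fold and 100 changed 4-fold. For age on western diet, 64 of the 2-fold and 94 of the 4-fold changes were recovered with 11 false calls. For haplotype the numbers were 56, 95 and 4, for age without the diet 63, 97 and 10, and for the diet in adults 55, 98 and 10. No recovered change had the wrong sign. For age on western diet, a simulated shift of the interferon list was called and 0 of 48 unmoved lists were. Each simulated gene varied independently of the others, so correlation between genes and structure shared by libraries were left out. The false calls of genes and lists here are therefore no measure of those in the real data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Results for some genes are not reported here.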

Results

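The series asks how a western diet alters kidney transcripts in hypertensive mice that overexpress a human angiotensin receptor type 1. TPM were compared in 6 groups of 4 libraries. These were Hap-I adults, aged Hap-I mice and Hap-II adults on western diet, Hap-I adults and aged Hap-I mice without it, and C57 adults. Depth is unknown, since TPM carry no read totals. The number of genes above 0 was 17443 ± 1039 in Hap-I adults on western diet (SD, n = 4), 16828 ± 446 in aged Hap-I mice on the diet, 16723 ± 626 in Hap-II adults on the diet and 18211 ± 191 in C57 adults. Transcripts encoded by the mitochondrial genome took 30.4 ± 4.03 percent of TPM in Hap-I adults on western diet, 27.7 ± 6.77 in the aged group, 24.4 ± 3.06 in Hap-II adults and 15.2 ± 2.13 in C57 adults. Correlations of libraries within a group lay between 0.926 and 0.991. The Y-linked gene Eif2s3y reached 5 TPM in 3 of 4 libraries of Hap-I adults on western diet, 2 of 4 of the aged group on the diet, 2 of 4 of Hap-II adults, all 8 libraries labelled Hap-I without the diet and 0 of 4 C57 adults. The labels give no sex.

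The 8 libraries labelled Hap-I adult and Hap-I aged without western diet held abundant neuronal and glial transcripts and almost none of the nephron. Snap25, a synaptic vesicle fusion protein (ENSMUSG00000027273, GRCm38 chromosome 2, 136713453 to 136782428), stood at 1977 ± 294 TPM in the adult and 2162 ± 121 TPM in the aged libraries (SD, n = 4), against 1.12 ± 0.43 TPM in C57 adults. The median of 12 neuronal markers was 331 ± 31.3 TPM in the adult and 348 ± 11.9 TPM in the aged libraries, 0.662 ± 0.26 TPM in C57 adults and at most 0.228 TPM in any of the 12 libraries on western diet. Medians of 7 astrocyte markers were 210.5 ± 15.0 and 285 ± 28.5 TPM in the 8 libraries, and those of 7 oligodendrocyte markers 184 ± 20.2 and 261 ± 44.5 TPM. Conversely, the median of 13 nephron markers was 0.119 ± 0.109 and 0.338 ± 0.314 TPM there, against 271 ± 69.8 TPM in C57 adults. Umod, the thick ascending limb protein uromodulin (ENSMUSG00000030963, chromosome 7, 119462711 to 119479282), averaged 0.807 TPM over these 8 libraries and 933 TPM over the other 16. Of 39 markers, 38 separated the 8 libraries from the other 16 without overlap. The exception was Aqp4, an astrocyte water channel that the collecting duct also expresses. The marker lists were written after these values had been seen. These libraries are called below by their labels, and every comparison that uses them against other groups compares different tissue contents.

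**Figure D1:**
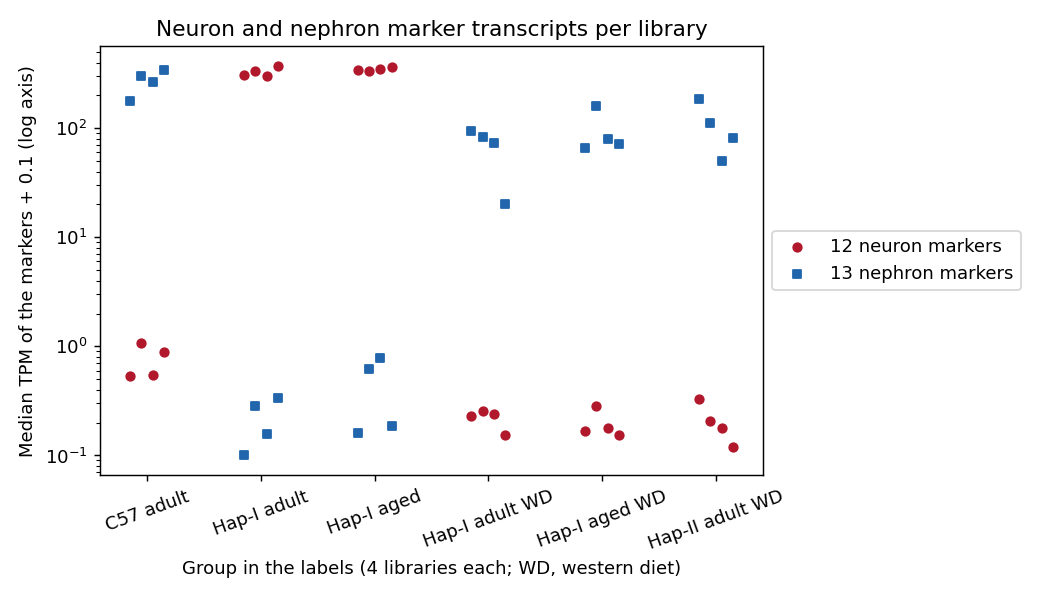
Median TPM of 12 neuronal and 13 nephron markers in each library, plus 0.1 on a log axis, with 4 libraries per labelled group. The 8 libraries labelled Hap-I adult and Hap-I aged have neuronal medians of at least 304 TPM before the offset, and the highest C57 adult library has 0.966 TPM.

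Between Hap-I and Hap-II adults on western diet, few genes differed. Sap18, a subunit of the Sin3 corepressor complex (ENSMUSG00000021963, chromosome 14, 57798180 to 57806638), was higher in Hap-I by 1.91 ± 0.23 log2 units (SE), at 34.5 ± 14.8 against 8.30 ± 3.18 TPM (SD, n = 4, adjusted p = 0.000129). Eif3j1, a translation initiation factor subunit, was higher by 0.67 (6.19 ± 0.403 against 3.54 ± 0.626 TPM, adjusted p = 0.0374). The mitochondrial gene mt-Nd3 (ENSMUSG00000064360, mitochondrial genome, 9459 to 9806) was lower, with a log2 change of -2.02 ± 0.348 and 3507 ± 641 against 14191 ± 2226 TPM (adjusted p = 0.0151). Krcc1 (ENSMUSG00000053012, chromosome 6, 71271677 to 71285319) was lower with a log2 change of -1.11, at 23.0 ± 3.06 against 50.9 ± 7.73 TPM (adjusted p = 0.0374). In all, 4 genes were higher and 7 lower in Hap-I, 8 of them by at least 2-fold, and 915 genes had an unadjusted p under 0.05. The rest, outside the naming rule and chosen after their values were seen, were Gm4737, Gm10052, Gm28438, Pcna-ps2, Pla2g12b, Procr and Dok3.

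Of the 11 genes, 7 had a near-identical copy elsewhere in the genome. Gm4737 (ENSMUSG00000048087, chromosome 16, 46152985 to 46155077), an intronless copy of the adenosylhomocysteinase gene Ahcy (chromosome 2, 155059310 to 155074497), stood between 96.8 and 134 TPM in the 4 Hap-II libraries and between 0 and 0.941 TPM in Hap-I adults on the diet. The sum of Gm4737, Ahcy and Gm9826 was 129 ± 13.1 TPM in Hap-I and 166 ± 33.9 TPM in Hap-II (log2 change -0.34, adjusted p = 0.738). Sap18 and Sap18b summed to 94.0 ± 10.7 and 124 ± 22.2 TPM (log2 change -0.38, adjusted p = 0.738). For mt-Nd3 and its nuclear copy Gm28438 the sums were 13929 ± 3442 and 14353 ± 2169 TPM (log2 change -0.06, adjusted p = 0.987). Eif3j1 with Eif3j2 (log2 change -0.21), Gm10052 with Hnrnpa1 and its other copies (-0.58) and Pcna-ps2 with Pcna (0.06) also missed the threshold after summing, with adjusted p = 0.746, 0.738 and 0.948. With copies summed, 2 genes passed limma's test and 906 had an unadjusted p under 0.05. Krcc1 and Dok3, which had no copy found, kept their changes but also missed the threshold in this fit (adjusted p = 0.121 and 0.136), so that a lost call alone does not show an effect of copies. Pla2g12b, a secreted phospholipase A2 family member (ENSMUSG00000009646, chromosome 10, 59403660 to 59421976), was higher in Hap-I by 0.99 ± 0.161, and Procr, the endothelial protein C receptor (ENSMUSG00000027611, chromosome 2, 155751117 to 155755471), was lower with a log2 change of -0.90 ± 0.15 (adjusted p = 0.0388 for both). Both were weakly expressed, Pla2g12b at 1.735 ± 0.611 TPM in Hap-I and 0.379 ± 0.342 TPM in Hap-II, and Procr at 1.466 ± 0.446 and 3.629 ± 1.015 TPM. Neither was called, with copies unsummed, when the 8 libraries labelled Hap-I without western diet were left out.

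**Figure D2:**
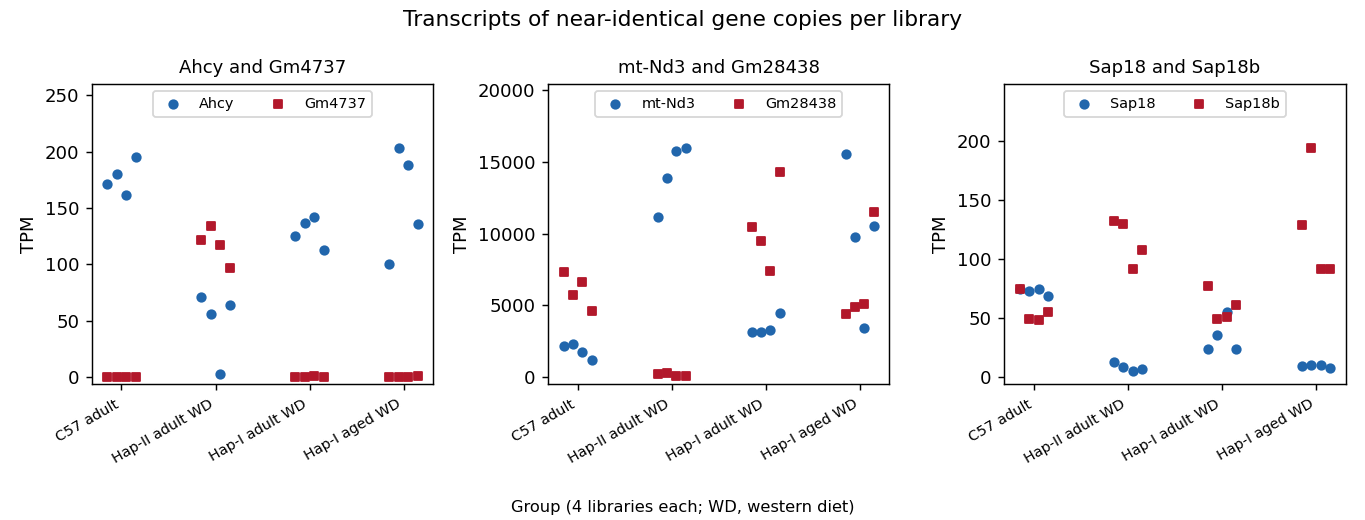
TPM of a gene (circles) and its near-identical copy (squares) in each of 4 libraries per group, on linear axes. Gm4737 is at 96.8 TPM or more in the 4 Hap-II libraries, and Gm28438 averages 162 TPM there against 10421 TPM in Hap-I adults on western diet.

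None of the panel genes passed the haplotype test. Agtr1a, the mouse angiotensin receptor, stood at 11.6 ± 2.70 TPM in Hap-I and 13.3 ± 5.77 TPM in Hap-II adults (log2 change -0.13 ± 0.296, adjusted p = 0.916), and Ren1, renin, at 20.9 ± 5.52 and 23.3 ± 10.6 TPM (log2 change -0.08, adjusted p = 0.988). Angptl4, an inhibitor of lipoprotein lipase, was at 9.43 ± 4.00 and 25.2 ± 13.2 TPM (log2 change -1.28, adjusted p = 0.717), and Per2, a clock repressor, at 5.35 ± 2.47 and 2.14 ± 1.93 TPM (log2 change 1.08, adjusted p = 0.737). The median of all genes was -0.177 and moved to 0.001 under median-of-ratios rescaling and -0.002 under quantile normalization. The calls were then 5 higher and 5 lower, and 7 higher and 4 lower.

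Of the 49 lists, 13 were called by camera between the haplotypes, with almost no member passing by itself. Immediate early genes lay 0.39 above the median of all genes in Hap-I (0 of 19 members called, adjusted p = 1.95e-07) and genes higher in male kidney 1.03 above it (0 of 13, adjusted p = 2.32e-05). Matrix genes (0 of 30, 0.19 above, adjusted p = 0.00137), stromal markers (0 of 12, 0.34 above, adjusted p = 0.000496), urothelial markers (0 of 8, 0.36 above) and Y-linked genes (0 of 4, 0.75 above) also ranked as higher. The fatty acid oxidation list ranked lower in Hap-I (0 of 34, -0.26 from the median of all genes, adjusted p = 0.00132), as did sodium transport (0 of 25, -0.29), distal convoluted tubule (0 of 10, -0.43) and intercalated cell markers (0 of 10, -0.43). Mitochondrially encoded genes ranked higher (median log2 change 0.154), with 1 of 13 lower, or 1 higher and 1 lower adjusted over the list alone. In the other 12 lists 0 members passed when adjusted over the list alone. The clock list (median -0.047) and the bile acid and xenobiotic list (-0.155) were ranked higher against a negative median. All 13 had adjusted p = 0.921 with an estimated correlation, and fry called 0 lists.

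Single libraries moved these counts. The 11 genes became 7, 5, 7 and 7 without Hap-I libraries 1, 2, 3 and 4, and 7 without Hap-II library 1. The 13 lists became 7 without Hap-I library 3, 4 without Hap-II library 1 and 6 without Hap-II library 2. Without the 8 libraries labelled Hap-I with no western diet, 7 genes and 8 lists were called, the genes being Sap18, Krcc1, Gm4737, Gm28438, Pcna-ps2, Tusc3 and Gm8203, of which Gm8203 is a further uncertain copy, of H2afz.

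On western diet, several immune genes were higher in kidneys of aged than of adult Hap-I mice, with immunoglobulin genes at the top. Calls and p-values here use a spread shared by all 24 libraries. Without the 8 labelled Hap-I without the diet, 1 of 121 immune list genes was called in place of 38. Igkc, the kappa light chain constant region (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966), rose by 2.89 ± 0.565 log2 units (SE), from 114 ± 57.7 to 817 ± 351 TPM (SD, n = 4, adjusted p = 0.0136). Ighm, the mu heavy chain (chromosome 12, 113418558 to 113422730), rose by 3.27, from 9.59 ± 7.55 to 107 ± 82.4 TPM, and Igha, the alpha heavy chain, by 2.88, from 17.8 ± 6.02 to 152 ± 95.4 TPM. The variable and joining segments Igkv3-2, Igkv3-5, Igkj4 and Igkv12-46 rose by 4.85, 3.40, 3.09 and 2.91, and as members of a multigene family they are uncertain. Atp2b4, a plasma membrane calcium pump (ENSMUSG00000026463, chromosome 1, 133699457 to 133801041), rose by 3.10 ± 0.534, from 1.13 ± 0.55 to 22.6 ± 22.4 TPM.

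Of 14 B and plasma cell markers, 6 rose over all genes and 9 adjusted over the list alone, with a median 1.60 above that of all genes (camera adjusted p = 8.41e-06, but 0.589 with an estimated correlation). Counts adjusted over a list alone are descriptive here, since camera picked the lists from the same values. In the interferon list 11 of 24 rose, or 23 adjusted over the list alone, with a median 0.89 above that of all genes (adjusted p = 7.25e-14, again 0.589 with an estimated correlation). Among them, the signal transducer Stat2 rose by 1.13 ± 0.202, from 2.59 ± 1.21 to 6.67 ± 1.73 TPM, and the nucleic acid sensor Zbp1 by 1.28. Of 15 complement genes 7 rose, or 12 adjusted over the list alone. C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803) rose by 1.46 ± 0.351, from 18.3 ± 11.3 to 48.4 ± 14.9 TPM, C1qc by 1.64 and C4b by 1.54. Of 21 macrophage markers 7 rose, or 17 with 1 lower adjusted over the list alone, including Cd68 (log2 change 1.37) and Cx3cr1 (1.14). Among 17 T and NK cell markers 4 rose, or 8 adjusted over the list alone. Granzyme K, Gzmk (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908), rose by 1.04 ± 0.164, from 0.264 ± 0.182 to 1.61 ± 0.442 TPM, Lck from 1.49 ± 0.348 to 4.92 ± 1.65 TPM and Ccl5 by 1.19. The inflammation list had 6 of 24 higher, or 15 adjusted over the list alone, among them the adhesion molecules Vcam1 (1.12) and Icam1 (0.99). Of 10 genes of antigen presentation by MHC class II, 1 rose, or 3 adjusted over the list alone; it was the protease Ctss (1.48). Camera gave adjusted p = 4.63e-06 for complement, 4.23e-07 for macrophages, 0.000383 for T and NK cells, 3.03e-05 for inflammation and 0.0132 for MHC class II, and none of these 5 calls held with an estimated correlation (adjusted p = 0.616 for MHC class II and 0.589 for the others).

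A minority of vascular and matrix genes was also higher with age on western diet, by lists none of which held with an estimated correlation. Of 14 endothelial markers 4 rose, or 11 adjusted over the list alone (camera adjusted p = 4.18e-05, 0.589 with an estimated correlation). Pecam1 rose from 15.6 ± 5.43 to 33.1 ± 6.53 TPM and Cdh5, VE-cadherin, from 4.21 ± 1.96 to 10.1 ± 2.85 TPM (n = 4). Of 30 matrix genes 3 rose, or 12 adjusted over the list alone (adjusted p = 0.00112, estimated correlation 0.616), namely Tgfb1 (log2 change 0.87), Col4a2 (1.20) and Vim (1.20). Sources of reactive oxygen had 3 of 11 higher, Ncf1, Nos3 and Rac2, or 7 adjusted over the list alone (adjusted p = 0.00831, estimated correlation 0.59). Tubular injury genes had 1 of 24 higher, or 5 adjusted over the list alone (adjusted p = 0.0043, estimated correlation 0.616), and the unfolded protein list 0 of 22 on both counts (adjusted p = 0.037, estimated correlation 0.737, lost under median-of-ratios rescaling with adjusted p = 0.101). Oxidative phosphorylation (0 of 41, median log2 change -0.053), ribosomal proteins (0 of 45, -0.019), Y-linked genes (0 of 4, -0.592) and genes higher in male kidney (0 of 13, -1.28) ranked as lower. So did mitochondrially encoded genes (1 higher and 1 lower of 13, median 0.062) and thick ascending limb markers (1 lower of 11, median 0.050), against positive medians. In the limb list the gene was the tight junction protein Cldn10 (log2 change -0.58).

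Of the genes that fell with age on western diet, Sap18 had a log2 change of -1.69 and Tm2d1 and Ormdl1 of -0.89 and -0.82, and these 3 have copies. Msantd4 (-2.58), the Mediator subunit Med21 (-1.12), the integrin Itgav (-1.06), the ubiquitin-like modifier Ufm1 (-0.87) and Tex30 (-0.81) completed the named set. No panel gene passed. Agtr1a stood at 13.1 ± 7.86 TPM in aged and 11.6 ± 2.70 TPM in adult mice (log2 change 0.01 ± 0.296), and Ren1 at 21.01 ± 14.7 and 20.9 ± 5.52 TPM (adjusted p = 0.753). The NADPH oxidase subunit Cybb (log2 change 1.13, adjusted p = 0.0613), the cell cycle inhibitor Cdkn1a (1.13, adjusted p = 0.0767) and the tubular injury marker Lcn2 (1.25, adjusted p = 0.184) missed the threshold.

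**Figure D3:**
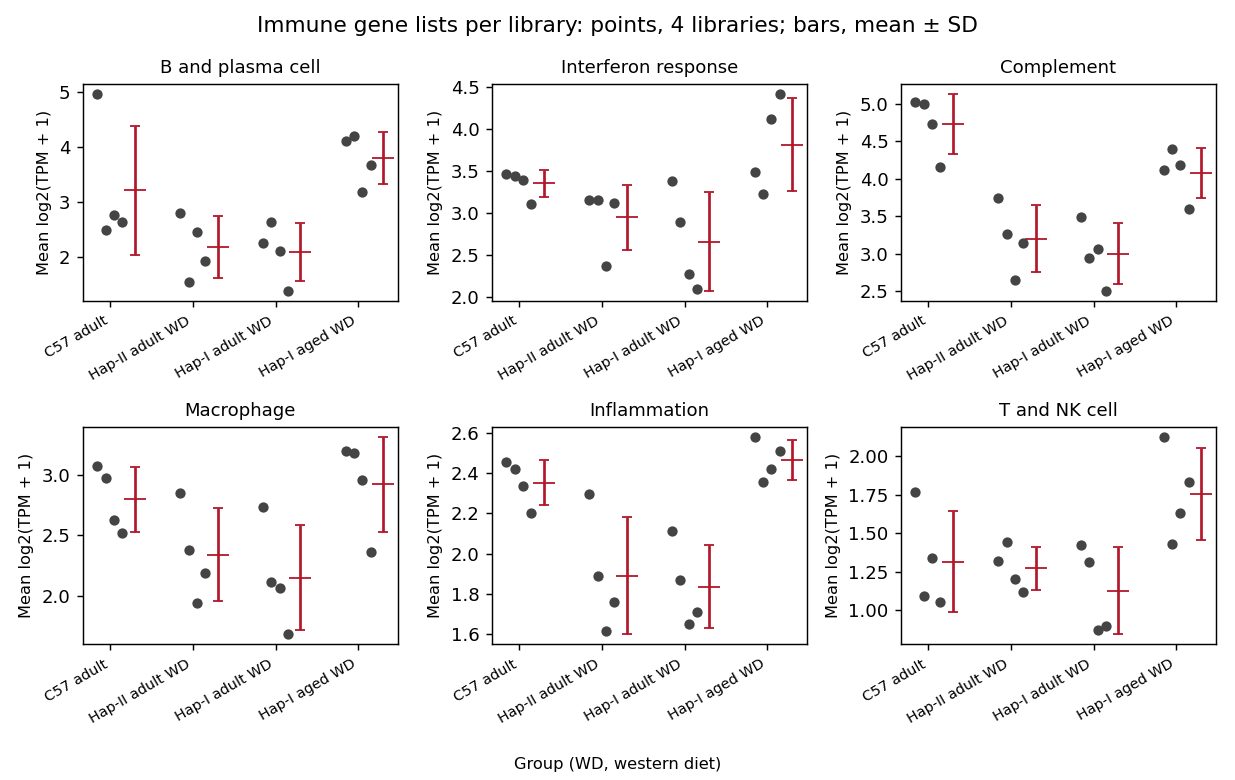
Mean log2(TPM + 1) over the genes of 6 immune lists in each library (points), with the group mean and SD (bars, n = 4), for C57 adults and the groups on western diet. For B and plasma cell markers the aged group averages 3.80 ± 0.474 and the adult Hap-I group 2.10 ± 0.527.

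With age on western diet, 443 genes were called in all, 411 higher and 32 lower, 203 of them by at least 2-fold. The count was 0 with the title number as a block, though the labels state no pairing. Over all genes the median was 0.26 and moved to 0.007 under median-of-ratios rescaling and -0.005 under quantile normalization, where the calls were 241 higher and 200 lower, and 114 higher and 148 lower. Of the 49 lists 18 were called. None of these held with an estimated correlation (adjusted p from 0.589 to 0.737), while fry called 14 lists, with adjusted p from 0.0021 to 0.0431 for the 12 that ranked higher here. List means per library did not overlap between the ages for B and plasma cells, complement, inflammation, T and NK cells, unfolded protein and ageing genes (exact permutation p = 0.0286 each, n = 4, the smallest possible, 0.215 after adjustment over the lists). The number of genes depended on whether the 8 libraries labelled Hap-I without the diet were in the fit. Interferon means had an SD of 0.11 in the aged and 0.125 in the adult ones, against 0.554 and 0.59 on the diet. B and plasma cell means had SDs of 0.131 and 0.172 against 0.474 and 0.527. For these lists the 8 libraries varied less, which lowers a shared spread. Its effect on the counts was not separated from that of the smaller number of libraries. Without the 8 libraries 7 genes were called (Sap18, Gzmk, Themis2, Ifi209, Tusc3, ENSMUSG00000062783 and the uncertain Gm8203), 6 of which were also among the 443, and 18 lists. Every library moved the count, to 981, 112, 49 and 75 without adult libraries 1 to 4 and to 938, 129, 262 and 774 without aged libraries 1 to 4. Adult library 4 had the fewest genes above 0 in its group (15975) and its lowest interferon, complement, macrophage and B cell means. Without it, the median of all genes was 0.148, and the 121 genes of the 7 immune lists had a median log2 change of 0.726 in place of 0.826, with 5 called in place of 38.

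Between the libraries labelled Hap-I aged and Hap-I adult without western diet, which held neuronal and glial RNA, 58 genes were higher with age and 7 lower. Lct, lactase (ENSMUSG00000026354, chromosome 1, 128284756 to 128328318), rose by 1.53 ± 0.26 log2 units (SE), from 7.95 ± 4.88 to 22.1 ± 4.92 TPM (SD, n = 4, adjusted p = 0.006). The heparan sulfate sulfotransferase Ndst4 (ENSMUSG00000027971, chromosome 3, 125404076 to 125728899) rose by 1.03, from 5.21 ± 1.79 to 11.6 ± 3.06 TPM, the glycosyltransferase Galnt6 by 0.95, the protocadherin Pcdhga2 by 0.92 and the ephrin receptor Epha6 by 0.91. The diacylglycerol kinase Dgki rose by 0.90, Tmem88b by 0.87, from 24.1 ± 5.74 to 43.9 ± 3.16 TPM, and the node of Ranvier proteoglycan linker Hapln2 by 0.85. The dynein light chain Dynlt1b fell, with a log2 change of -0.95 and 25.5 ± 8.50 against 48.5 ± 3.40 TPM (adjusted p = 0.0461). Near-identical copies were not searched for in this comparison.

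Of the lists, 10 ranked as lower with age in these libraries, with 0 members called over all genes. They were the adrenal marker list (6 genes, 2 lower adjusted over the list alone, median log2 change -0.453, adjusted p = 5.1e-08), unfolded protein (22 genes, 2 lower alone, -0.165), immediate early genes (19, 1 lower alone, -0.122), stroma (12, 1 lower alone, -0.185), mitochondrially encoded genes (-0.183), matrix (-0.132), endothelium (-0.095), interferon (-0.088), tubular injury (-0.087) and oxidative phosphorylation (-0.062). With an estimated correlation the adrenal list, which holds catecholamine synthesis genes, had adjusted p = 0.0685 and the others 0.935 to 0.96, and fry called 0. None of the panel genes passed, among them Agt (7.87 ± 2.85 TPM aged, 9.36 ± 3.34 TPM adult) and Per2 (14.3 ± 0.251 and 9.55 ± 1.95 TPM). At an unadjusted p under 0.05 there were 1034 genes, and 8 of the 65 called changed at least 2-fold. The median of all genes, 0.105, moved to -0.009 under median-of-ratios rescaling with 14 genes higher and 5 lower, and to -0.003 under quantile normalization with 14 and 8. The 65 became 219 without adult library 2, 41 without aged library 1 and 35 without aged library 3.

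The diet comparison in Hap-I adults set libraries rich in kidney transcripts against libraries rich in neuronal and glial transcripts. Kap, an androgen-regulated proximal tubule protein (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762), was at 61875 ± 29142 TPM on western diet and 3.75 ± 3.67 TPM in the libraries labelled without it (log2 change 13.89 ± 0.788 SE, n = 4, adjusted p = 2.05e-13). The plasma glutathione peroxidase Gpx3 stood at 11569 ± 2195 against 7.55 ± 2.73 TPM, Akr1c21 at 2366 ± 648 against 0.173 ± 0.205 TPM, and Miox, an enzyme of inositol breakdown, at 1526 ± 395 against 0.536 ± 0.576 TPM. In the other direction, Snap25 was at 0.303 ± 0.263 against 1977 ± 294 TPM (log2 change -10.58), Camk2a at 0.326 ± 0.458 against 1399 ± 86.3 TPM and Hpca at 0.117 ± 0.11 against 1459 ± 415 TPM. Slc17a7, a vesicular glutamate transporter, was listed at 0 in the 4 libraries on the diet and stood at 569.9 ± 117 TPM in the other 4. All 18 proximal tubule markers and all 11 thick ascending limb markers were higher, by medians of 6.57 and 2.93, as were 9 of 10 intercalated cell markers and 9 of 12 principal cell markers, with 1 lower. In the fatty acid oxidation list 21 of 34 were higher and 2 lower, and in the bile acid and xenobiotic list 18 of 25 and 2; all these counts were the same adjusted over the list alone. Agtr1a was at 11.6 ± 2.70 against 0.37 ± 0.14 TPM (log2 change 3.18), Ren1 was higher by 4.20 and Nox4 by 5.85, and Fn1 was lower with a log2 change of -3.10. Agt, Ace, Lcn2, Cpt1a and Per2 did not pass.

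In all, 12183 genes were called in adults, 2566 higher and 9617 lower, with 9674 changed at least 2-fold. Over all genes the median of -1.08 moved to -0.089 under median-of-ratios rescaling, where 5389 were higher and 6305 lower, and to 0.091 under quantile normalization, where 6113 were higher and 5617 lower. Camera called 31 lists, none with an estimated correlation (adjusted p = 0.142 for the proximal tubule, at most 0.629 in the called lists). In the 4 libraries on the diet, the neuronal marker median was 0.119 ± 0.046 TPM against 331 ± 31.3 TPM, so that diet and tissue content changed together.

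In aged Hap-I mice the diet comparison had the same contrast of tissue content, with neuronal medians of 0.096 ± 0.059 TPM on the diet and 348 ± 11.9 TPM without. Gpx3 was at 16566 ± 6818 against 14.6 ± 8.16 TPM (log2 change 10.13 ± 0.35 SE, n = 4, adjusted p = 1.47e-17), Miox at 2101 ± 810 against 2.23 ± 1.73 TPM and Kap at 35254 ± 31817 against 48.4 ± 44.4 TPM. Snap25 was listed at 0 on the diet against 2162 ± 121 TPM, and the myelin gene Mobp stood at 0.034 ± 0.067 against 777 ± 82.0 TPM. All 18 proximal tubule markers were higher (median log2 change 6.66), 10 of 11 thick ascending limb and 9 of 10 intercalated cell markers too. So were 20 of 24 interferon genes, with 1 lower, and 12 of 14 B and plasma cell markers, led by Igkc (817 ± 351 against 1.71 ± 1.05 TPM). These counts were the same adjusted over the list alone. Of the panel, Agtr1a (log2 change 3.20), Ren1 (3.86), Ace (1.97) and Lcn2 (2.46) were higher, Fn1 (-2.20), Arntl (-2.84) and Per2 (-1.05) lower, and Agt, Cdkn1a and Scd1 did not pass. Under quantile normalization Per2 had a log2 change of 0.159. There were 3118 genes higher and 9191 lower. The median of all genes, -0.974, moved to -0.098 with 5403 higher and 6302 lower under median-of-ratios rescaling, and to 0.047 with 6031 and 5755 under quantile normalization. Camera called 33 lists, none with an estimated correlation (adjusted p = 0.273 for the proximal tubule, 0.312 for the interferon list).

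The comparison of Hap-I with C57 adults, both without western diet, asks what the transgene does, and again set libraries rich in neuronal and glial transcripts against libraries rich in nephron transcripts. Snap25 (1977 ± 294 against 1.12 ± 0.43 TPM, log2 change 9.88 ± 0.157 SE, n = 4, adjusted p = 3.29e-23), Camk2a (9.38) and Slc17a7 (8.88) were higher in the libraries labelled Hap-I. Kap (3.75 ± 3.67 against 36373 ± 9221 TPM, log2 change -13.29), the kallikrein Klk1 (-11.40), Miox (-11.14) and Umod (0.16 ± 0.32 against 2175 ± 574 TPM, log2 change -10.86) were lower. All 18 proximal tubule, 11 of 11 thick ascending limb and 10 of 10 intercalated cell markers were lower, with 11 of 12 principal cell, 10 of 11 adipocyte and 8 of 8 urothelial markers, and as many adjusted over the list alone. Agtr1a stood at 0.37 ± 0.14 against 23.7 ± 4.18 TPM (log2 change -4.16), Ren1 at 0.163 ± 0.112 against 72.1 ± 14.7 TPM (-5.96) and Nox4 at 0.742 ± 0.363 against 192 ± 68.9 TPM, while Fn1 and Cdkn1a did not pass. In all, 6937 genes were higher and 3894 lower. The median of all genes, 0.404, moved to 0.090 with 5842 higher and 5006 lower under median-of-ratios rescaling, and to -0.036 with 5404 and 5633 under quantile normalization. Camera called 32 lists and none with an estimated correlation (adjusted p = 0.33 for the proximal tubule, at most 0.604). The human transgene itself was not analysed here.

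The difference of the diet effect between aged and adult Hap-I mice was called for 4 genes, with 1523 at an unadjusted p under 0.05. Sap18 had a difference of -1.93 ± 0.325 log2 units (SE, adjusted p = 0.029). Its means in adults were 34.5 ± 14.8 TPM on the diet and 64.2 ± 6.88 without, and in aged mice 9.41 ± 1.23 and 76.2 ± 9.10 (SD, n = 4). Wdfy1, an endosomal FYVE domain protein (ENSMUSG00000073643, chromosome 1, 79702262 to 79776143), had a difference of 2.44 ± 0.437 (adjusted p = 0.0487), from 6.26 ± 3.57 and 18.0 ± 2.90 TPM in adults and 15.9 ± 6.05 and 7.54 ± 3.41 TPM in aged mice. Gm16867 (-2.29, adjusted p = 0.00747) and the gene without a symbol ENSMUSG00000062783 (1.26, adjusted p = 0.00747) lie outside the naming rule and were chosen after their values were seen. Because 8 of the 16 libraries held neuronal and glial transcripts, each diet effect here also includes the tissue difference. The contrast equals the age difference on the diet minus the age difference in libraries of other tissue content. It therefore gives no estimate of how a diet effect changes with age.

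Of the lists, 18 were called for this difference, with 0 members called over all genes. Relative to the median of all genes, 0.15, which moved to 0.007 and -0.010 under median-of-ratios rescaling and quantile normalization, the interferon list lay 1.03 higher (20 of 24 adjusted over the list alone, adjusted p = 1.87e-14). B and plasma cell markers lay 1.73 higher (6 of 14 alone), complement 0.87 (4 of 15), endothelium 0.70 (7 of 14), macrophages 0.69 (8 of 21, with 2 lower) and matrix 0.61 (4 of 30). These lists also ranked as higher with age on western diet, a difference that this contrast contains. For the 18 lists the adjusted p ran from 0.435 to 0.77 with an estimated correlation, and fry called 0 lists with adjusted p from 0.0708 to 0.663. The 4 genes became 19 without western diet library 1 of the adults or 4 of the aged mice, and 36 and 7 without adult library 2 and aged library 2 of those labelled without the diet. They became 2 without any of adult libraries 1 and 4 and aged libraries 1 and 3 labelled without the diet.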

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

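No test in this part was chosen after the result was seen. Panel genes and library measures, in 128 combinations with a group, were examined for a single library set apart by Dixon's ratio. The limit was 0.829 for 4 libraries. The library measures were the number of genes above 0, the mitochondrially encoded share and the share of the most abundant genes. By chance about 1 in 20 such groups would give an outlier, and 8 were found, so chance alone may account for these, and no library was removed.

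Lcn2, a tubular injury marker, stood at 7.68 TPM in library 4 labelled Hap-I adult without western diet, against 0.209 to 0.616 TPM in the other 3. In the same library Fn1 was at 26.7 TPM (others 22 to 22.6 TPM), and in library 2 of this group Ace was at 30.3 TPM (others 3.67 to 7.44 TPM). In C57 adults library 1 was lowest for Nox4, at 89.4 TPM against 215 to 236 TPM, and for Cpt1a, at 55.3 TPM against 131 to 147 TPM. Cybb stood at 6.26 TPM in Hap-II library 1 on western diet (others 2.04 to 2.59 TPM), Cdkn1a at 4.9 TPM in Hap-I adult library 1 on the diet (others 1.97 to 2.03 TPM) and Angptl4 at 47.1 TPM in aged Hap-I library 3 on the diet (others 10.9 to 15.7 TPM).

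For the difference of the diet effect by age, Sap18 (log2 difference -1.93), ENSMUSG00000062783 (1.26), Wdfy1 (2.44) and Gm16867 (-2.29) were called. Of 100 groupings of the libraries, the real one included, 4 called at least as many genes, with 11 in the highest other. This result is borderline, since the other groupings were drawn at random and the level was not adjusted over the comparisons. With a pseudocount of 0.1, 0 genes were called for the real grouping. Chance was therefore not excluded. The grouping with 11 genes, more than the real 4, also leaves a structure of the samples open. The neuronal and glial transcripts in 8 of these 16 libraries leave the role of the diet unresolved. Sap18 has a near-identical copy, Sap18b, which makes its value uncertain.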

How the results depend on the processing

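Settings that left out the 8 libraries, filtered on the other 16, used Y-linked expression, left out 2 libraries, removed pseudogenes, summed copies or used C57 were chosen after seeing the data. Total gene counts for the diet and for Hap-I against C57 moved by less than 1.5 times, though their splits into higher and lower genes and their lists moved more, and those for age, haplotype and the difference of the diet effect moved further. Where no reason is given, the cause was not tested. For the diet in adults, lists went from 31 to 20 with median-of-ratios rescaling, 16 with quantile normalization and 0 with an estimated correlation, which also gave 0 for the diet in aged mice and for Hap-I against C57. For age without the diet, the 65 genes became 3 with a pseudocount of 0.1, 262 with no filter, 27 with a filter of 5 TPM, 19 with median-of-ratios rescaling, 22 with quantile normalization, 29 without mitochondrially encoded genes, 22 also without pseudogenes, 550 with array weights and 2 with only the compared groups. Its 10 lists became 0 with an estimated correlation and 0 with fry. For age on the diet, the 443 genes became 272 with no filter, 267 with a filter of 5 TPM, 262 with quantile normalization, 2680 with array weights, 2 with only the compared groups, 7 without the 8 libraries, 8 without them and with Y-linked expression as a covariate, 4 without them and with the filter on the other 16, 189 without the 2 libraries with fewest genes and 0 with limma and the title number as a block (2083 at an unadjusted p under 0.05). Its 18 lists became 0 with an estimated correlation. For haplotype, the 11 genes became 6 with a filter of 5 TPM, 83 with array weights, 6 with only the compared groups, 7 without mitochondrially encoded genes and pseudogenes, 7 without the 8 libraries, 6 without them and with the Y-linked covariate, 6 without the 2 libraries, 1 with the block and 2 with copies summed. Its 13 lists became 8 with a pseudocount of 0.1, 8 without the 8 libraries, 5 without them and with the Y-linked covariate, 0 with an estimated correlation and 0 with fry. For the difference of the diet effect, the 4 genes became 0 with a pseudocount of 0.1, 24 with no filter, 2 with a filter of 5 TPM, 2 with each rescaling, 2 without mitochondrially encoded genes, 2 also without pseudogenes and 880 with array weights, and its 18 lists 0 with an estimated correlation and 0 with fry. Against C57, the 9327 genes of Hap-I on the diet became 5555 with median-of-ratios rescaling and 4988 with quantile normalization, and the 7095 of Hap-II 4372 and 4105. Without the 8 libraries they were 8750 and 5591, and with the Y-linked covariate as well 3279 and 2211. Without the 2 libraries with fewest genes, Hap-II gave 4623. Lists there became 0 with an estimated correlation, and 42 and 34 with fry. Leaving out a single library gave 11806 to 12051 genes and 30 to 34 lists for the diet in adults, 11925 to 12339 and 33 to 36 for the diet in aged mice, 35 to 219 and 7 to 11 for age without the diet, 49 to 981 and 13 to 23 for age on the diet, 5 to 10 and 4 to 16 for haplotype, 10222 to 10560 and 30 to 32 for Hap-I against C57, and 2 to 36 and 13 to 22 for the difference of the diet effect. Against C57 it gave 7746 to 9480 and 20 to 24 for Hap-I on the diet and 4082 to 8456 and 18 to 23 for Hap-II. Among the genes the naming rule picked, some changes reversed in sign. In the diet comparison in adults these were Col1a1 (from -0.515 to 0.048 with median-of-ratios rescaling and 0.377 with quantile normalization), mt-Cytb (0.775 to -0.052) and mt-Nd6 (0.672 to -0.077, both with quantile normalization), and in aged mice Per2 (-1.05 to 0.159). For Hap-I on the diet against C57 they were Rpl30 (-0.669 to 0.292), Rpl4 (-0.885 to 0.075) and Ier3 (-0.85 to 0.066) with median-of-ratios rescaling, and Ugt2b38 (2.30 to -0.059) and Slc7a13 (4.62 to -0.314) without the 8 libraries and with the Y-linked covariate. In that setting Ddx3y (-0.058), Eif2s3y (-0.110) and Kdm5d (-0.017) fell near 0 by construction, since they form the covariate, which says nothing about stability. Title numbers were not taken to pair the samples, since the labels state no pairing and correlations of same-number libraries ran from -0.032 to 0.533 over 3 pairs of groups, with 1, 3 and 3 of 4 over 0.1. The best match had its own number in 2, 5 and 4 of 8 libraries.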

Other observations

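Apart from the summing of copies and the regrouping of libraries, all tests in this part were chosen after the result was seen.

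Because the libraries labelled Hap-I without western diet held neuronal and glial transcripts, C57 adults were used as an alternative group without the diet. Line, diet and title series coincide in these contrasts, so no difference can be assigned to the diet, and Y-linked expression was low in all 4 C57 libraries but in 1 of 4 Hap-I and 2 of 4 Hap-II libraries on the diet. The median of all genes was -0.68 for Hap-I and -0.50 for Hap-II adults on western diet against C57, with 8940 and 6615 genes lower against 387 and 480 higher. Under median-of-ratios rescaling 2957 and 2288 were lower against 2598 and 2084 higher. Most lists therefore hold many lower genes, and their medians are given relative to that of all genes. All 11 adipocyte genes were lower in both, with relative medians of -3.27 and -3.30 (estimated-correlation adjusted p = 0.695 and 0.614). The lipogenic enzyme Fasn stood at 3.08 ± 1.94 TPM in Hap-I and 3.26 ± 2.32 TPM in Hap-II against 70.02 ± 63.7 TPM in C57 (SD, n = 4). Of 25 sodium transport genes 24 and 20 were lower (relative medians -1.21 and -1.01), or 16 and 12 under median-of-ratios rescaling, and the list did not hold with an estimated correlation (adjusted p = 0.788 and 0.805). Fn1 stood at 2.07 ± 1.48 and 2.05 ± 0.54 against 24.9 ± 10.2 TPM, with 25 and 26 of 30 matrix genes lower (relative medians -0.90 and -1.03, estimated-correlation adjusted p = 0.391 and 0.291). Mitochondrially encoded genes were higher, 12 and 9 of 13, or 2 and 3 under quantile normalization (estimated-correlation adjusted p = 0.106 and 0.175). Adjusted over the list alone the counts were the same but for sodium transport in Hap-I, with 25 lower. Ren1 was lower in both (20.9 ± 5.52 and 23.3 ± 10.6 against 72.1 ± 14.7 TPM). In all 9327 and 7095 genes were called, 8750 and 5591 without the 8 libraries, 3279 and 2211 without them and with Y-linked expression as a covariate, and 4082 for Hap-II without its library 3.

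Exactly 2 genes of the table were under 0.2 TPM in the same 7 libraries and over 2 TPM in the other 17. They were Tusc3 (ENSMUSG00000039530, chromosome 8, 39005845 to 39165114), at most 0.009 TPM against 3.15 to 149.6 TPM, and the processed pseudogene Gm8203, uncertain as a near-identical copy of H2afz (chromosome 6, 116173737 to 116174123), at most 0.121 TPM against 15.2 to 85.1 TPM. The 7 were all 4 Hap-I adult libraries on western diet, libraries 2 and 3 labelled Hap-I adult and library 2 labelled Hap-I aged. The cause was not tested.

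For the neuronal and glial transcripts in 8 libraries, the absence of western diet was excluded as an explanation. C57 adults, also without the diet, had a highest neuronal median that was 0.318 percent of the lowest in the 8 libraries. Admixture of another tissue into kidney RNA was excluded too, since nephron markers there had a median of 0.0836 percent of their level in the other 16. RNA of another organ, likely brain, under kidney labels remained open, with 38 of 39 markers apart. Whether samples, libraries or columns were exchanged cannot be told from these values.

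For the immune genes higher in aged than adult Hap-I mice on western diet, age itself was not tested apart from these explanations. Low values in the adult group stay open, since complement means per library were 2.50 to 3.48 there, 3.60 to 4.40 in aged mice and 4.16 to 5.03 in C57 adults. B and plasma cell means were 1.38 to 2.64, 3.175 to 4.21 and, in 3 of 4 C57 libraries, 2.49 to 2.76. C57 library 1 stood at 4.97, above every aged library. Interferon means of aged mice and C57 adults overlapped (3.225 to 4.42 and 3.115 to 3.465), as did T and NK cell means (1.43 to 2.12 and 1.055 to 1.77). Among the 16 libraries the 121 immune genes had a median log2 change of 0.76 with Y-linked expression as a covariate. The quartiles over genes were 0.509 and 1.16, and the median was 91.4 percent of that without the covariate. It cannot exclude Y-linked expression, since only library 1 of the adults was under 5 TPM of Eif2s3y. Its interferon mean, 3.383, lay between those of aged libraries 1 and 2, also under 5 TPM (3.485 and 3.225). Interferon means of the others were 2.098 to 2.896 in adults and 4.122 and 4.422 in aged mice. For B and plasma cells the libraries under 5 TPM stood at 2.254 in the adult and 4.119 and 4.208 in aged mice. Of the 121 genes 38 were called with all 24 libraries and 1 without the 8, with or without the covariate. With the title number as a block, 0 were called and the median was 0.826. Scaling of the libraries goes with part of the shift, since under quantile normalization the median was 0.55 (quartiles over genes 0.28 and 0.902), against 0.826, with 14 genes called. That scaling did not remove the shift. It was applied to all 24 libraries, 8 of them with other tissue content, and no rescaling within the other 16 was run. Scaling was therefore not excluded as the cause. A lower share of tubule cells was not settled for B and plasma cell markers. Their means relative to stromal markers were 0.833 ± 0.443 in aged and -0.385 ± 0.411 in adult libraries (exact permutation p = 0.0286, n = 4). Of all lists theirs had the largest age difference, 1.7, against 0.482 for stroma. The test was chosen after that was seen, so it describes a larger rise than in stroma and does not decide the cause. The other immune lists were not set against stroma. Means of stromal and podocyte markers were also higher in aged libraries, by 0.482 and 0.589. For the other immune lists a lower share of tubule cells stays open too.

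Between Hap-I and Hap-II adults, reads shared between near-identical copies fit the data for part of the calls. Of 7 called genes with copies, 0 stayed called after their copies were summed, and the change of Sap18 went from 1.91 to -0.38. The 4 called genes without copies kept their changes though 2 missed the threshold in that fit. For Pcna-ps2 and Gm10052 the lost call says little, since a more abundant copy dominated the sum. Pcna stood at 28.5 TPM in Hap-I and 25.3 TPM in Hap-II, against 0.011 and 2.52 TPM for Pcna-ps2. Hnrnpa1 stood at 35.7 and 40.2 TPM, against 0 and 16.4 TPM for Gm10052. A chromosome segment that differs between the lines was left undecided. At their own positions 2 of 11 called genes lay on chromosome 2, against 8.19 percent of genes tested (Fisher exact p = 0.226). With families placed by their most abundant member it was 3 of 10 (Fisher exact p = 0.0425), and the chromosome was picked because genes were seen there.

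Libraries were grouped in all 35 ways, the real one included, to ask whether chance can be excluded. It was for the diet in adults (1 of 35 with at least the real 12183 genes, highest other 4773), the diet in aged mice (1, with 12309 against 7096) and Hap-I against C57 (1, with 10831 against 1), where the tissue contents differ. It was not for age without the diet (2, with 65 against 68), age on the diet (3, with 443 against 942) or haplotype (3, with 11 against 1588). For haplotype, groupings with 1588 and 1133 genes, many times the real 11, point to a structure of the samples. Both placed the 3 libraries under 5 TPM of Eif2s3y on the same side, while the other 3 groupings that did so called 0, 1 and 1 genes and no further grouping but the real one called more than 1. The groupings with 1588 and 1133 genes also placed the 2 libraries with the fewest genes above 0 together on the other side. These were Hap-I library 4 (15975) and Hap-II library 3 (15999). The grouping with 0 genes did so too. A part for Y-linked expression or for the number of genes above 0 in this structure stays open.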
